A study of Mus musculus with 6 samples.

How the data were processed

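Whole adrenal glands were taken from mice in 2 groups, WT and VEGF/LysM, with 3 samples each. Per the labels' protocols, RNA was extracted from fresh glands with a column kit, only samples of high RNA integrity went on, and libraries followed the Smart-seq2 approach, which makes full-length cDNA that does not mark strand. Per the submitters' processing notes, kallisto, DESeq2 1.36.0 and the mouse build mm10 were used; the role of each tool, the version of kallisto and the annotation are not given in the sources used here. The deposited file holds 1 table of whole-number counts per gene and library, not normalised, as the values themselves show. How the authors made whole numbers from transcript estimates is not given in the sources used here. Reads from overlapping or antisense genes cannot be told apart without strand, and reads of near-identical genes may be split between them. Each column was matched to its sample by the title. The table has 54532 genes, of which 54409 identifiers matched a symbol in the gene name table; the others took at most 0.0938% of any library's counts.

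Counts were scaled by TMM after the filterByExpr filter (minimum count 10, minimum total count 15), which kept 16300 genes. TMM factors were 1.02 to 1.05 in 5 libraries and 0.84 in WT replicate 3. edgeR 4.0.16 under R 4.3.3 fitted the quasi-likelihood model with group as the only term, and p values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are VEGF/LysM minus WT. Standard errors come from the fitted model and 95% intervals from its t distribution. CPM values are TMM-scaled unless said to be of the library total. The common biological coefficient of variation was 0.365. Library totals ran from 16476879 to 18671950 counts, so genes near 1 CPM rest on few reads and carry more counting error than abundant ones. An exact permutation of 3 against 3 cannot give p below 0.1, so single values were not tested alone. Coordinates are from the GENCODE annotation of GRCm38, the assembly that mm10 names. No library pair was identical.

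Before the data were examined, 35 gene lists were fixed for the gland's cell types, vessels, steroid synthesis, the targeted gene, blood, stress and library quality; 34 had at least 3 tested members. camera (limma 3.58.1) with a preset correlation of 0.01 tested each against all other genes, two-sided, adjusted over the 34 lists. The rule for named genes, fixed at the same time, took 13 genes always (Vegfa, Lyz2, Plvap, Kdr, Flt1, Col4a1, Col4a2, Cyp11b2, Star, Cyp11b1, Th, Adgre1, Csf1r). It added the genes of largest change past the threshold (there were none) and, in a list called without passing members, the 2 genes with the smallest p. As fewer than 5 genes passed, it also added the 10 with the smallest p and a mean of at least 1 CPM. Of the genes this rule named, 1 is not reported here. Hepatocyte and B cell lists were written after the values were seen and serve only to describe libraries.

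The same steps were tested on simulated counts with the real means, library sizes and gene-wise spread, in which 200 of 16300 genes were changed and 1 list was raised 1.5-fold. In the simulation of all 6 libraries, 0% of 1.5-fold, 2% of 2-fold, 48% of 4-fold and 80% of 8-fold changes were called, with 6 false calls among 72. In the simulation without WT replicate 3, on 16659 genes, 2%, 40%, 82% and 94% were called, with 15 false calls among 126. Both shares of false calls exceed the threshold of 0.05. Apart from the set changes, all simulated libraries were drawn from the same mean per gene, so none stood apart as WT replicate 3 does. The shares called and falsely called may therefore differ in the real libraries. The raised list was called in both simulations, with 0 of the other lists, but simulated genes are independent, which real lists are not.

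The alternatives were DESeq2 size factors, upper-quartile and library-size scaling, no filter, a stricter filter (1 CPM in 3 libraries), a replicate block, each library left out in turn, medulla and adipocyte covariates, 1 surrogate variable (sva 3.50.0), removal of mitochondrial and haemoglobin genes, DESeq2 1.42.0, limma-voom with and without sample weights, a threshold of 0.1, a fold minimum of 1.2, camera with an estimated correlation and fry, which asks whether a list's genes move, on balance, one way and compares them with no other genes. A sex term was not fitted because no library had more than 2 Y-linked counts. Added after the data were seen were a robust fit, leaving out both libraries with liver transcripts, and a hepatocyte covariate.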

Results

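Transcript levels were measured in whole mouse adrenal glands by bulk RNA sequencing, in 3 samples labelled WT and 3 labelled VEGF/LysM. The series compares them to learn what VEGF-A from macrophages does for the gland as a whole. The labels do not describe the allele, and they do not say whether the replicates came from separate animals. Each p therefore measures the spread between these samples, which may be technical. The deposited counts summed to between 16476879 (VEGF/LysM replicate 3) and 18671950 (VEGF/LysM replicate 2) per library, and 22230 to 23491 genes had at least 1 count. Y-linked transcripts gave at most 2 counts in any library, while Xist, the RNA of the inactive X chromosome, gave 6687 to 15966.

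WT replicate 3 held liver, kidney and lymphocyte transcripts at levels far from those of the other 5 libraries. Alb, which encodes serum albumin, stood at 39912 CPM of the library total in that library and at 0.06 and 0.16 CPM in WT replicates 1 and 2. On the same scale it stood at 174 CPM in VEGF/LysM replicate 3 and at 1.09 and 0.75 CPM in VEGF/LysM replicates 1 and 2. The 30 genes of a hepatocyte list written after the values were seen took 8.42% of the counts of WT replicate 3, 0.0398% of VEGF/LysM replicate 3 and at most 0.00325% of any other library. Slc34a1, a phosphate transporter of kidney tubules, had 214 counts in WT replicate 3, 18 in VEGF/LysM replicate 3 and 0 in the other libraries. Miox had 103 and 8 counts in the same libraries, and Umod 40 and 7, with at most 1 count in any other library. The first principal component, with 64.2% of the variance, placed WT replicate 3 at 119 and the other libraries between -33.8 and -7.79. The second, with 13.0%, placed VEGF/LysM replicate 3 at -53.2 and the others between 5.85 and 18.1.

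**Figure D1:**
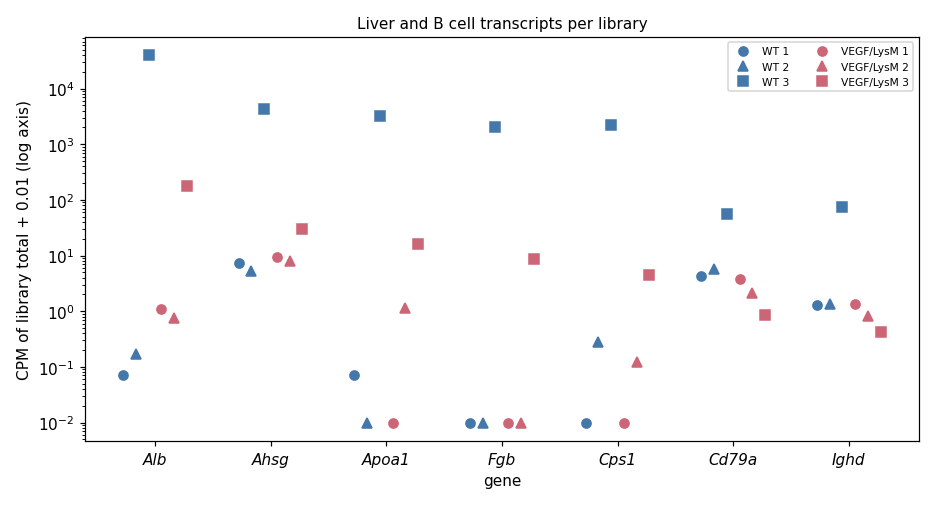
CPM of the library total plus 0.01 on a log axis for 5 liver transcripts (Alb, Ahsg, Apoa1, Fgb, Cps1) and 2 B cell transcripts (Cd79a, Ighd), with 1 point per library, WT in blue and VEGF/LysM in red. WT replicate 3 is the highest library for each gene, with Alb at 39912 CPM, and VEGF/LysM replicate 3 is next for the liver transcripts, with Alb at 174 CPM.

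Vegfa, the gene in the group's name, did not differ detectably between the whole glands of VEGF/LysM and WT. It encodes a growth factor of endothelial cells (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369, minus strand, GRCm38). Vegfa averaged 289 ± 45.8 CPM in WT (SD, n = 3) and 291 ± 182 in VEGF/LysM (SD, n = 3), a log2 fold change of 0.0095 with a 95% interval of -0.96 to 0.98. Its VEGF/LysM libraries read 180, 193 and 501 CPM, so the high value came from replicate 3, and without that library the log2 fold change was -0.63. The direction of Vegfa also turned with DESeq2 size factors (-0.0022). A whole gland holds many Vegfa-producing cells other than macrophages, so these values are a weak check of the labels. Lyz2, the lysozyme gene of myeloid cells also called LysM (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand), was at 186, 275 and 263 CPM in WT and at 132, 111 and 134 CPM in VEGF/LysM. Its log2 fold change was -0.94 ± 0.19 (SE), lower in 3 of 3 VEGF/LysM samples than in any WT sample, and did not pass over all genes in edgeR's test (adjusted p = 0.999). Lyz2 may share reads with its close copy Lyz1. How many reads are shared was not measured, so the Lyz2 count is uncertain. Lyz1 averaged 3.55 ± 3.10 CPM in WT and 13.7 ± 1.2 in VEGF/LysM (SD, n = 3).

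No gene passed the test between VEGF/LysM and WT. edgeR's quasi-likelihood test called 0 of 16300 genes at an adjusted p of 0.05, with a smallest adjusted p of 0.999. At an unadjusted p under 0.05 it found 459 genes, 142 higher and 317 lower in VEGF/LysM. If every p were exact, chance alone would give 815. Other splits of these 6 libraries into 3 and 3 gave 389 to 1415 such genes. limma-voom called 0 genes (224 at an unadjusted p under 0.05), limma-voom with sample weights called 0 (300), and DESeq2 called 3 (703). The 3 DESeq2 genes, named after their values were seen, were Mup-ps19, Gm16157 and Adgrf1, with 74, 68 and 69 counts in WT replicate 3 and 0 in the other 5 libraries. The groups did not overlap for 970 genes, 5.95% of those tested, against 10% by chance. The median 95% interval reached 0.61 log2 units to either side, and 77.4% of genes had an interval under 1 log2 unit to either side. Without WT replicate 3 edgeR called 1 gene, without VEGF/LysM replicate 3 it called 0 (209 at an unadjusted p under 0.05), and without both it called 0 (378). The 1 gene was Sumo2, a ubiquitin-like modifier (adjusted p = 0.0368), named after its values were seen. It stood at 41.2 and 59.7 CPM in WT replicates 1 and 2 but at 6.61 CPM in WT replicate 3, below the 8.12 to 11.1 CPM of VEGF/LysM.

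The 10 genes with the smallest p and a mean of at least 1 CPM did not pass over all genes (adjusted p = 0.999 for each in edgeR's test). Mmrn1, a multimerin of lymphatic endothelium and platelets (chromosome 6, 60924976 to 60989378), had a log2 fold change of -2.72 ± 0.52 (SE), from 3.19 to 0.479 CPM. Smad9, a BMP signal transducer (chromosome 3, 54755582 to 54801257), stood at 31.8 to 38.1 CPM in WT and 53.1 to 62.9 CPM in VEGF/LysM, a log2 fold change of 0.72 ± 0.14. Cxcr4, the receptor of the chemokine Cxcl12 (chromosome 1, 128588199 to 128592293), stood at 33.7 to 46.2 CPM in WT and 17.8 to 23.1 CPM in VEGF/LysM (-0.96 ± 0.19). Snrpe, a spliceosome protein, had -1.08 ± 0.22. Ly6k had -3.38 ± 0.79, Lctl 1.60 ± 0.37, Tgm3 2.36 ± 0.57, 1700001C02Rik 1.81 ± 0.40 and Gm2004, which belongs to a family of similar genes, -1.99 ± 0.40. Lyz2 was the other member of the 10. In each of the 10 genes the 3 VEGF/LysM values lay on 1 side of the 3 WT values. As the 10 were picked by their p in these same libraries, this adds no support. Over all genes tested the groups did not overlap for 5.95%, against 10% by chance.

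**Figure D2:**
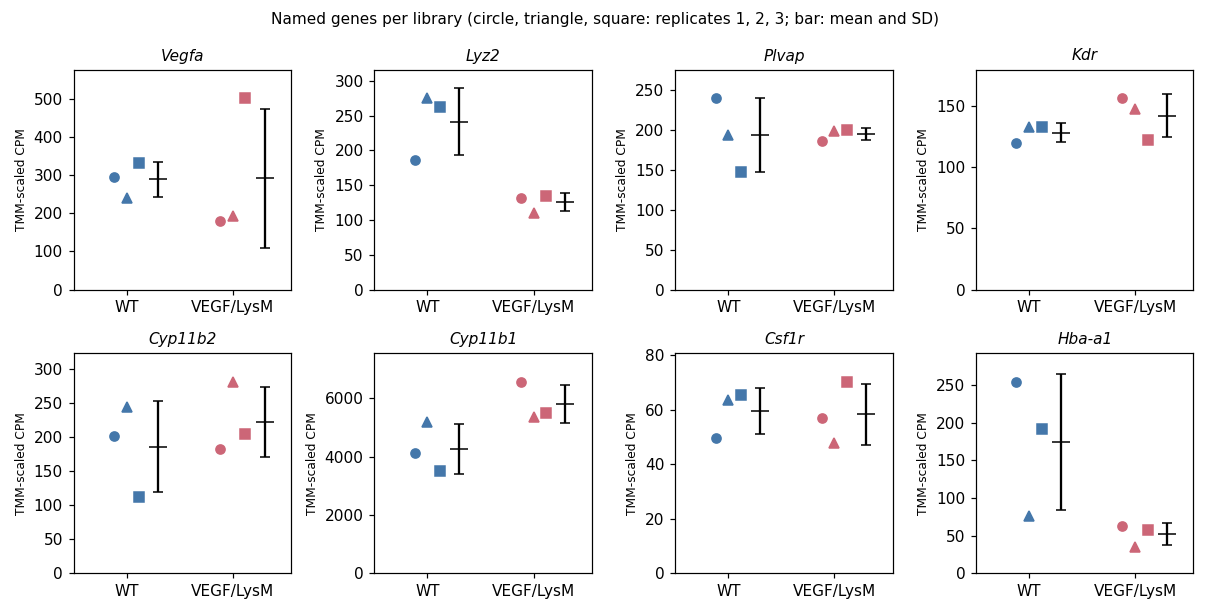
TMM-scaled CPM of 8 genes, with the replicates of each group as circle, triangle and square and a bar for the mean and SD (n = 3). Lyz2 (241 against 126 CPM) and Hba-a1 (174 against 52.1 CPM) had VEGF/LysM points below each WT point, and the other panels but Cyp11b1 show overlapping groups; none passed the test over all genes.

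Of 34 gene lists tested, camera with a preset correlation of 0.01 called 17, with 6 higher and 11 lower in VEGF/LysM. With an estimated correlation camera called 0 lists (1 at an unadjusted p under 0.05, smallest adjusted p 0.516), and fry, which does not compare a list with other genes, called 0 (smallest adjusted p 0.76, or 0.827 for change in either direction). Ranges of adjusted p over a list's alternatives include fry. No member of any list passed over all genes. Adjusted over the list alone, 5 erythrocyte genes, Lyz2 among the macrophage genes and Mmrn1 among the large-vessel endothelial genes passed. Without WT replicate 3 camera called 9 lists, of which 5 were among the 17 in the same direction, without VEGF/LysM replicate 3 it called 16 (11 shared), and without both it called 14 (7 shared). The erythrocyte, lymphocyte and neutrophil, heat shock and proliferation lists were called lower in each of the 6 fits that left out 1 library.

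Erythrocyte transcripts were lower in VEGF/LysM, with a list median log2 fold change of -1.42 over 7 tested genes, each below 0 (camera, adjusted p = 1.41e-10; adjusted p = 0.516 with an estimated correlation). Adjusted over the list alone, 5 of the 7 passed and over all genes 0. Hba-a1, an alpha globin gene, averaged 174 ± 90.2 CPM in WT and 52.1 ± 14.7 in VEGF/LysM (SD, n = 3), a log2 fold change of -1.74 ± 0.43 (SE). Its near-identical copy Hba-a2 had -1.91 ± 0.48, and the split of reads between both is uncertain. WT replicate 2 had 75.9 CPM of Hba-a1, near the highest VEGF/LysM value of 63.4 CPM. The list's leave-one-out fits gave adjusted p from 2.36e-12 to 0.000246, with a median of -0.93 without WT replicate 1. That library also held 178 counts of Slc4a1, an untested member of the list, against 1 to 6 elsewhere.

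The lymphocyte and neutrophil list was called lower in VEGF/LysM, with a median log2 fold change of -2.25 and 16 of 17 tested genes below 0 (camera, adjusted p = 2.67e-08; adjusted p = 0.573 with an estimated correlation). Its 5 untested genes were the neutrophil markers S100a8, S100a9, Retnlg, Ly6g and Cxcr2, so the call says nothing about neutrophils. WT replicate 3 carried most of the size: the list's median in that library was 3.48 log2 units above WT replicates 1 and 2, and without it the list's median was -0.28 (adjusted p = 0.00541; 2.05e-12 to 0.76 over 21 alternatives). Ighm, an immunoglobulin heavy chain, averaged 383 ± 343 CPM in WT and 84.1 ± 35.2 in VEGF/LysM (SD, n = 3), a log2 fold change of -2.18, or -1.16 without WT replicate 3. The MHC class II list, for antigen presentation, was called lower with 7 of 7 genes below 0 and a median of -0.27 (adjusted p = 0.0355; adjusted p = 0.641 with an estimated correlation). Ciita, its transcriptional activator, had a log2 fold change of -0.87 ± 0.81 (SE) and H2-DMa -0.48 ± 0.44, and the direction of Ciita turned without WT replicate 3 (0.15). The call of that list ended without WT replicate 2, WT replicate 3, VEGF/LysM replicate 1 or VEGF/LysM replicate 2 (adjusted p = 0.323, 0.398, 0.455 and 0.527), while its list median in VEGF/LysM replicate 3 was 0.81 above WT replicates 1 and 2. Interferon-stimulated genes were called lower with 17 of 20 below 0 and a median of -0.17 (adjusted p = 0.0291; adjusted p = 0.641 with an estimated correlation), with Bst2 at -0.43 ± 0.17 and Ifi27l2a at 0.54 ± 0.30 (0.18 without VEGF/LysM replicate 3). That call ended without the same 4 libraries (adjusted p = 0.694, 0.0917, 0.474 and 0.0899).

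Macrophage markers as a list were not called (median -0.0016 over 25 genes, adjusted p = 0.417), although leaving out VEGF/LysM replicate 3 gave a call lower (adjusted p = 0.0384; 0.00936 to 0.852 over 21 alternatives). Lyz2 was the 1 member that passed adjusted over the list alone. Csf1r, the receptor for the macrophage growth factor CSF1, had a log2 fold change of -0.028 ± 0.19 (SE), which turned to 0.0042 with upper-quartile scaling and 0.054 with library size only. Adgre1, the macrophage marker F4/80, had 0.31 ± 0.32. Inflammatory and NF-kB target genes were not called (median -0.19 over 15 genes, adjusted p = 0.0876). They were called lower without WT replicate 1 (adjusted p = 0.0232) or VEGF/LysM replicate 3 (adjusted p = 0.0104; 0.0104 to 0.784 over 21 alternatives), while without WT replicate 3 the list's median turned to 0.22 (adjusted p = 0.694).

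Endothelial genes did not pass singly. Plvap, the protein of fenestral diaphragms, had a log2 fold change of 0.01 ± 0.20 (SE; 194 and 195 CPM), Kdr, a VEGF receptor, 0.15 ± 0.14 (128 and 142 CPM) and Flt1, another, 0.19 ± 0.20 (81.0 and 92.5 CPM). The 95% interval of Plvap was -0.45 to 0.47. The fenestrated capillary list was called higher with 13 of 16 genes above 0 and a median of 0.20 (adjusted p = 0.0253; adjusted p = 0.516 with an estimated correlation), with Cd300lg at 0.25 ± 0.14 and Fabp4 at 0.33 ± 0.21. Its call ended without WT replicate 2, WT replicate 3, VEGF/LysM replicate 1 or VEGF/LysM replicate 2 (adjusted p = 0.095, 0.158, 0.161 and 0.101). Large-vessel and lymphatic endothelial genes were called lower with 12 of 16 below 0 and a median of -0.11 (adjusted p = 0.0438; adjusted p = 0.622 with an estimated correlation). Its smallest p values were those of Mmrn1 and of Prox1, a lymphatic transcription factor that went the other way at 0.49 ± 0.25. That call ended without WT replicate 2, WT replicate 3, VEGF/LysM replicate 1 or VEGF/LysM replicate 3 (adjusted p = 0.152, 0.347, 0.0863 and 0.496). VEGF pathway genes (median 0.032, 20 genes, adjusted p = 0.208), pan-endothelial markers (median -0.033, 24 genes, adjusted p = 0.934) and HIF targets of the hypoxia list (median -0.16, 20 genes, adjusted p = 0.0563) were not called. The hypoxia list was called lower without WT replicate 1 (adjusted p = 0.0439; 0.0247 to 0.76 over 21 alternatives). The camera direction of the pan-endothelial list was up, against a median and mean below 0.

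Basement membrane genes were called higher with 22 of 25 above 0 and a median of 0.14 (adjusted p = 0.0251; adjusted p = 0.641 with an estimated correlation). Col4a1 and Col4a2, which encode chains of type IV collagen, had log2 fold changes of 0.14 ± 0.17 and 0.094 ± 0.16 (SE). Lamc3 had 0.48 ± 0.21, and Col18a1 had -1.74 ± 0.81 with 918 CPM in WT replicate 3 and 86.5 to 148 CPM in the other libraries. Integrin and mechanosensing genes were called higher with 22 of 28 above 0 and a median of 0.15 (adjusted p = 0.0177; adjusted p = 0.622 with an estimated correlation), with Crim1 at 0.35 ± 0.16 and Itgav at 0.34 ± 0.16. Without WT replicate 1, WT replicate 3 or VEGF/LysM replicate 1 both calls ended (basement membrane adjusted p = 0.0883, 0.427 and 0.176, integrin adjusted p = 0.0632, 0.222 and 0.101), and the basement membrane call also ended without VEGF/LysM replicate 2 (adjusted p = 0.0899). Pericyte and smooth muscle genes were called lower with 7 of 14 below 0 and a median of -0.059 (adjusted p = 0.0253; adjusted p = 0.516 with an estimated correlation). Acta2, smooth muscle actin, had -1.12 ± 0.36 and Myh11, smooth muscle myosin, -1.08 ± 0.46, which became -0.69 and -0.45 without WT replicate 3, and the list's median in WT replicate 3 was 0.54 above WT replicates 1 and 2. Its call ended without WT replicate 2, WT replicate 3, VEGF/LysM replicate 1 or VEGF/LysM replicate 3 (adjusted p = 0.123, 0.106, 0.101 and 0.0569). Interstitial matrix and fibrosis genes (median -0.038, 27 genes, adjusted p = 0.813) and capsule and fibroblast markers (median -0.0056, 17 genes, adjusted p = 0.555) were not called. The capsule list was called lower without VEGF/LysM replicate 2 (adjusted p = 0.0373) and higher without VEGF/LysM replicate 3 (adjusted p = 0.0202; 0.0202 to 0.905 over 21 alternatives).

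With the preset correlation the zona fasciculata, zona glomerulosa and X-zone lists of the cortex were called higher in VEGF/LysM, and with an estimated correlation none of them was. No member passed over all genes. Zona fasciculata markers had 11 of 13 genes above 0 and a median of 0.18 (adjusted p = 0.0291; adjusted p = 0.516 with an estimated correlation). Cyp11b1, the last enzyme of corticosterone synthesis, stood at 3500 to 5177 CPM in WT and 5348 to 6555 CPM in VEGF/LysM, a log2 fold change of 0.44 ± 0.23 (SE). Aldh1a1 had -1.77 ± 0.97 with 568 CPM in WT replicate 3 and 41.5 to 76.6 CPM elsewhere, and its direction turned without that library (0.56). Without WT replicate 2, VEGF/LysM replicate 1, VEGF/LysM replicate 2 or VEGF/LysM replicate 3 the zona fasciculata call ended (adjusted p = 0.124, 0.0724, 0.101 and 0.082). Zona glomerulosa markers had 17 of 23 genes above 0 and a median of 0.18 (adjusted p = 0.0253; adjusted p = 0.641 with an estimated correlation), with Kcnk9 at 0.38 ± 0.26 and Atp2b3 at 0.45 ± 0.29. Cyp11b2, aldosterone synthase, averaged 186 ± 66.7 CPM in WT and 222 ± 51.2 in VEGF/LysM (SD, n = 3), a log2 fold change of 0.26 with a 95% interval of -0.47 to 0.99. In WT replicate 3 the glomerulosa list's median was 0.93 below WT replicates 1 and 2, and without that library the call ended with the direction turned (adjusted p = 0.398; list median 0.05). That call also ended without VEGF/LysM replicate 1 or VEGF/LysM replicate 3 (adjusted p = 0.141 and 0.0547). The X-zone list, for an inner cortical layer of the mouse adrenal, had 6 of 6 genes above 0 and a median of 0.43 (adjusted p = 0.0253; adjusted p = 0.622 with an estimated correlation), with Cyp2f2 at 0.82 ± 0.39 and Pik3c2g at 0.97 ± 0.68. VEGF/LysM replicate 3 stood apart in both, with 1712 CPM of Cyp2f2 (450 to 788 elsewhere) and 198 CPM of Pik3c2g (14.7 to 79.6 elsewhere), and without it their log2 fold changes were 0.29 and 0.24. Pik3c2g had 0.52 without WT replicate 3 and turned to -0.21 without both libraries. The list's call ended without WT replicate 3, VEGF/LysM replicate 2 or VEGF/LysM replicate 3 (adjusted p = 0.392, 0.0676 and 0.182).

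Cholesterol synthesis genes were called lower with 22 of 24 below 0 and a median of -0.66 (camera, adjusted p = 8.05e-07; adjusted p = 0.625 with an estimated correlation). Hmgcs1, which makes HMG-CoA for the sterol pathway, was at 663 CPM in WT replicate 3 and 191 to 283 CPM elsewhere (-0.96 ± 0.43, SE), and Pmvk, a mevalonate pathway kinase, at 83.7 and 20.5 to 29.7 CPM (-1.06 ± 0.43). Both shrank without WT replicate 3, to -0.28 and -0.36. Without WT replicate 3 the list's median was -0.0017 and the call ended (adjusted p = 0.784; 9.61e-09 to 0.784 over 21 alternatives). The steroidogenesis list was not called (median 0.11, 24 genes, adjusted p = 0.231), and Star, the cholesterol carrier that starts steroid synthesis, had 0.27 ± 0.25. Glucocorticoid response genes were not called (median -0.49, 13 genes, adjusted p = 0.0727). They were called lower without WT replicate 1, WT replicate 2 or VEGF/LysM replicate 3 (adjusted p = 0.0183, 0.0212 and 0.0202) and higher without WT replicate 3 (adjusted p = 0.0109; 0.0109 to 0.833 over 21 alternatives). Chromaffin markers of the medulla were not called (median 0.11, 24 genes, adjusted p = 0.106) and were called higher without WT replicate 1 or VEGF/LysM replicate 1 (adjusted p = 7.44e-05 and 0.00998; 7.44e-05 to 0.961 over 21 alternatives). Without WT replicate 2, WT replicate 3 or VEGF/LysM replicate 3 the camera direction of the chromaffin list turned down (adjusted p = 0.961, 0.784 and 0.872). Without both libraries with liver transcripts it was called lower (median -0.20, adjusted p = 0.0212). Th, the first enzyme of catecholamine synthesis, had 0.32 ± 0.31. Schwann and neuron genes were called lower with 12 of 14 below 0 and a median of -0.45 (adjusted p = 0.029; adjusted p = 0.641 with an estimated correlation). Prph, a neuronal filament, read 83.1, 2.58 and 59.8 CPM in WT and 2.70, 24.9 and 9.36 CPM in VEGF/LysM, and Erbb3 read 109 CPM in WT replicate 3 and 8.25 to 12.1 CPM elsewhere. The Schwann and neuron call ended without WT replicate 1, WT replicate 3 or VEGF/LysM replicate 1 (adjusted p = 0.769, 0.347 and 0.592).

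Cell cycle genes were called lower with 19 of 20 below 0 and a median of -0.34 (camera, adjusted p = 1.11e-06; adjusted p = 0.622 with an estimated correlation), and without WT replicate 3 the list's median was -0.21 (adjusted p = 0.00229). Top2a, a topoisomerase of dividing cells, had -0.75 ± 0.31 (SE) and Rrm2, a ribonucleotide reductase subunit, -0.61 ± 0.24 (-0.44 and -0.37 without WT replicate 3). Heat shock genes were called lower with 10 of 13 below 0 and a median of -0.41 (adjusted p = 0.000487; adjusted p = 0.622 with an estimated correlation), and without WT replicate 3 the list's median was -0.14 (adjusted p = 0.0192). The near-identical Hspa1a and Hspa1b had -1.42 ± 0.43 and -1.55 ± 0.50, with 80.4 and 245 CPM in WT replicate 3 (-0.86 and -0.73 without it), and their split of reads is uncertain. Nuclear respiratory chain genes were called lower with 24 of 26 below 0 and a median of -0.14 (adjusted p = 0.0253; adjusted p = 0.715 with an estimated correlation), with Sdhc at -0.28 ± 0.21 and Sdhd at -0.22 ± 0.22. That call ended without WT replicate 1, WT replicate 3, VEGF/LysM replicate 1 or VEGF/LysM replicate 3 (adjusted p = 0.236, 0.173, 0.0724 and 0.755), and its direction turned in the last. Without both libraries with liver transcripts the respiratory chain list was called higher (median 0.094, adjusted p = 0.0479; 0.000149 to 0.76 over 21 alternatives). Not called were the mitochondrially encoded genes (median 0.12, 13 genes, adjusted p = 0.104), ribosomal proteins (median -0.065, 30 genes, adjusted p = 0.143) and adipocyte markers (median 0.012, 17 genes, adjusted p = 0.549). Without WT replicate 3 these were called higher, lower and higher (adjusted p = 0.000263, 0.00703 and 0.0212), and the mitochondrial list was also called higher without VEGF/LysM replicate 2 (adjusted p = 0.0334). Mitochondrial transcripts took 4.14% to 4.65% of the counts in WT and 4.80% to 5.71% in VEGF/LysM, higher in 3 of 3 VEGF/LysM samples than in any WT sample. This share of library totals, which can reflect RNA quality or composition, thus followed the groups and was not adjusted for. On the TMM scale the mitochondrial list did not follow the groups. Its median relative to WT replicates 1 and 2 was 0.52 in WT replicate 3. In VEGF/LysM replicates 1, 2 and 3 it was 0.35, 0.16 and 0.43. What the share reflects here was not tested. The immediate early list was not called either (median 0.036, 20 genes, camera direction down, adjusted p = 0.934). It was called higher without VEGF/LysM replicate 1 (adjusted p = 0.038) and lower without VEGF/LysM replicate 3 (adjusted p = 0.000171). Circadian clock genes (median 0.12, 18 genes, adjusted p = 0.396) and skeletal muscle markers (median -0.24, 6 genes, adjusted p = 0.934) were not called. Of 20 kidney, liver and pancreas markers, 6 were tested. The filter left out Fgb and Ttr among others, with 35293 and 38018 counts in WT replicate 3, so the list test did not cover them. The list was not called (median -1.02, 6 genes, adjusted p = 0.208) but was called lower without WT replicate 1 or WT replicate 2 (adjusted p = 0.0189 and 0.0273). WT replicate 3, at a list median 2.74 above WT replicates 1 and 2, carried these lower values, and without it the median turned to 0.66 (adjusted p = 0.389; 0.0189 to 0.76 over 21 alternatives). Of the sex-linked list, only Xist had enough counts to be tested (0.13).

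**Figure D3:**
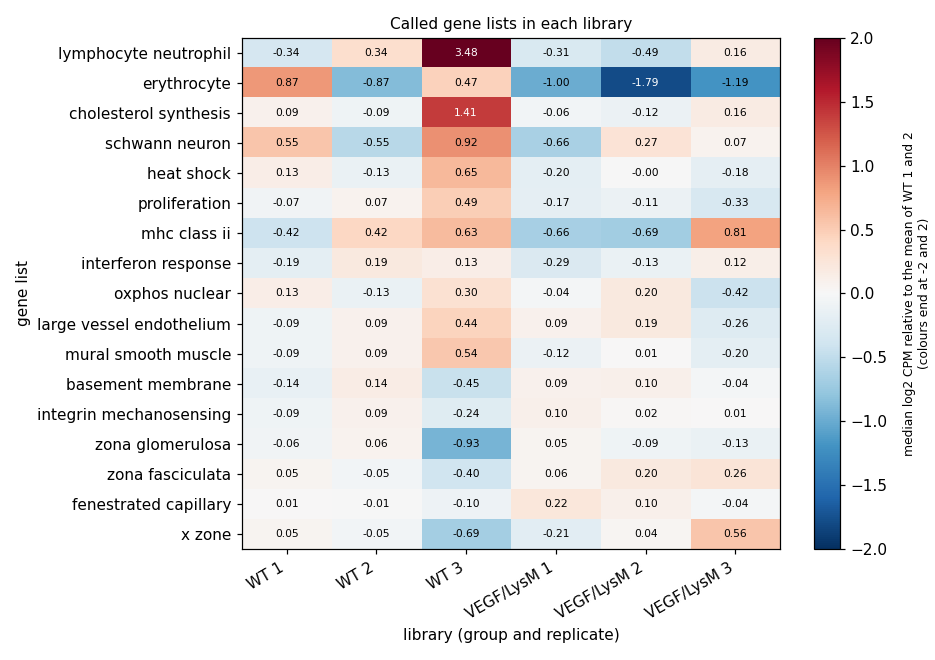
Median log2 CPM of the tested genes of each of the 17 called lists, per library, relative to the mean of WT replicates 1 and 2; the colour scale ends at -2 and 2, and the numbers give the value. WT replicate 3 reads 3.48 for the lymphocyte and neutrophil list and 1.41 for cholesterol synthesis, and the erythrocyte list reads -0.997, -1.79 and -1.19 in VEGF/LysM against 0.87, -0.87 and 0.47 in WT.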

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

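A robust fit, leaving out both libraries with liver transcripts and a hepatocyte covariate were chosen after the data were seen. edgeR's quasi-likelihood count of 0 genes (459 at an unadjusted p under 0.05) stayed at 0 in 22 of 24 alternatives. It was 0 to 1 over the 6 fits that left out 1 library, with the 1 gene without WT replicate 3, and DESeq2 called 3. The 17 called lists became 8 to 18 when 1 library was left out (18, 13 and 9 without WT replicates 1, 2 and 3, and 8, 13 and 16 without VEGF/LysM replicates 1, 2 and 3). They became 8 without a filter, 7 with 1 surrogate variable, 10 with a hepatocyte covariate, 0 with an estimated correlation and 0 with fry. The surrogate variable set WT replicate 3 (-0.90) against the other libraries (0.065 to 0.24). Deviations of same-numbered libraries from their group means correlated at 0.064, -0.014 and 0.25, and not every sample correlated best with its own number. WT replicate 3 lay far from its group and weighed on these deviations. They therefore cannot show whether the replicate numbers pair the samples. With a replicate block 0 genes (270 at an unadjusted p under 0.05) and 15 lists were called, all 15 among the 17, and the log2 fold change of Vegfa was -0.15. Over 54 named genes and their alternatives, 1250 of 1293 values kept their direction and side of the threshold. For the 17 called lists 228 of 357 values did, 128 lost the call and 1 was called in the other direction, and for the 17 lists not called 278 of 356 did and 34 gained a call, 4 of them with the direction turned. Values that changed follow in parentheses, as log2 fold changes of genes or list medians, whose sign can differ from camera's direction; except for fewer samples in a fit, the cause was not tested. With DESeq2 size factors, directions turned for Vegfa (-0.0022). With upper-quartile scaling, directions turned for Csf1r (0.0042). With library size only, calls ended for zona glomerulosa (0.21), interferon (-0.090) and respiratory chain (-0.064), calls were gained for glucocorticoid (-0.34) and directions turned for Csf1r (0.054). With no filter, calls ended for fenestrated capillary (0.20), large-vessel endothelium (-0.13), basement membrane (0.13), zona fasciculata (0.17), smooth muscle (-0.040), MHC class II (-0.28), interferon (-0.18), Schwann and neuron (-0.45) and respiratory chain (-0.14). Directions turned for skeletal muscle (-0.031) and immediate early (0.032) at that setting. With the stricter filter, calls were gained for hypoxia (-0.19). With a replicate block, calls ended for Schwann and neuron (-0.49) and respiratory chain (-0.16) and directions turned for Vegfa (-0.15). With the medulla covariate, calls ended for large-vessel endothelium (-0.014), zona glomerulosa (0.15), zona fasciculata (0.18), MHC class II (-0.32) and interferon (-0.16) and directions turned for Plvap (-0.016) and Vegfa (-0.19). With the adipocyte covariate, calls were gained for chromaffin (0.16) and hypoxia (-0.17) and directions turned for Vegfa (-0.072). With 1 surrogate variable, calls ended for fenestrated capillary (0.14), large-vessel endothelium (-0.056), basement membrane (0.086), integrins (0.061), cholesterol synthesis (-0.044), X-zone (0.25), smooth muscle (-0.092), MHC class II (-0.014), interferon (-0.092), Schwann and neuron (-0.31) and respiratory chain (-0.076). Calls were gained for mitochondrial (0.28) and ribosomal (-0.11) at that setting. Directions turned for Erbb3 (0.062), Aldh1a1 (0.44), Ciita (0.090), Csf1r (0.051), Plvap (-0.13), VEGF pathway (0.076), pan-endothelial (-0.013), zona glomerulosa (0.039), inflammation (0.21), neighbouring organs (0.56), skeletal muscle (0.26), immediate early (0.19) and glucocorticoid (0.19) at that setting. With DESeq2, directions turned for Vegfa (-0.0013). With limma-voom, directions turned for Vegfa (-0.15). With limma-voom with sample weights, directions turned for Aldh1a1 (0.30), Plvap (-0.051) and Vegfa (-0.25). Without both libraries with liver transcripts, calls ended for basement membrane (0.12), integrins (0.065), cholesterol synthesis (-0.10), smooth muscle (-0.096), Schwann and neuron (-0.60) and heat shock (-0.097). Calls were gained for macrophage (-0.19), adipocyte (0.28), immediate early (-0.23), mitochondrial (0.24) and ribosomal (-0.11) at that setting. Directions turned for Col18a1 (0.16), Erbb3 (0.081), Aldh1a1 (0.70), Pik3c2g (-0.21), Sdhc (0.024), Sdhd (0.11), Th (-0.16), Plvap (-0.16), Vegfa (-0.52), large-vessel endothelium (0.12), interstitial matrix (0.026), zona glomerulosa (-0.0021), X-zone (-0.099), chromaffin (-0.20), capsule (0.12), neighbouring organs (0.48), skeletal muscle (0.13), clock (0.026), glucocorticoid (0.025) and respiratory chain (0.094) at that setting. Of these lists, chromaffin (adjusted p = 0.0212, down) and respiratory chain (adjusted p = 0.0479, up) were called in the turned direction. With the hepatocyte covariate, calls ended for fenestrated capillary (0.15), large-vessel endothelium (-0.11), basement membrane (0.094), zona glomerulosa (0.073), X-zone (0.46), smooth muscle (-0.10), MHC class II (-0.15), interferon (-0.12) and Schwann and neuron (-0.28). Calls were gained for mitochondrial (0.24) and ribosomal (-0.090) at that setting. Directions turned for Aldh1a1 (0.16), Csf1r (0.034), Plvap (-0.066), pan-endothelial (-0.014), neighbouring organs (0.098), skeletal muscle (0.16), immediate early (0.094) and glucocorticoid (0.093) at that setting. With an estimated correlation or fry the calls of all 17 lists ended at unmoved medians, which were 0.20 for fenestrated capillary, -0.11 for large-vessel endothelium, 0.14 for basement membrane, 0.15 for integrins, 0.18 for zona glomerulosa, 0.18 for zona fasciculata, -0.66 for cholesterol synthesis, 0.43 for X-zone, -0.059 for smooth muscle, -0.27 for MHC class II, -2.25 for lymphocytes, -0.17 for interferon, -0.45 for Schwann and neuron, -1.42 for erythrocyte, -0.41 for heat shock, -0.34 for proliferation and -0.14 for respiratory chain. Over the fits that left out 1 library, genes whose direction turned ranged from -2.50 to 0.19 for Erbb3, -2.26 to 0.56 for Aldh1a1, -1.87 to 0.15 for Ciita, -0.057 to 0.52 for Th, -0.047 to 0.32 for Flt1, -0.0047 to 0.50 for Cyp11b2, -0.18 to 0.079 for Csf1r, -0.15 to 0.19 for Plvap and -0.63 to 0.24 for Vegfa. The medians of lists whose call or direction changed ranged from -0.022 to 0.15 for VEGF pathway, 0.088 to 0.21 for fenestrated capillary, -0.093 to 0.023 for pan-endothelial, -0.33 to -0.018 for large-vessel endothelium, 0.057 to 0.30 for basement membrane, -0.14 to 0.10 for interstitial matrix, 0.051 to 0.21 for integrins and 0.050 to 0.31 for zona glomerulosa. Others ranged from 0.20 to 0.32 for zona fasciculata, -0.88 to -0.0017 for cholesterol synthesis, 0.10 to 0.74 for X-zone, -0.045 to 0.38 for chromaffin, -0.33 to 0.22 for capsule, -0.26 to -0.086 for smooth muscle, -0.18 to 0.046 for macrophage and -0.93 to -0.048 for MHC class II. Others ranged from -0.30 to -0.12 for interferon, -0.53 to 0.22 for inflammation, -0.16 to 0.31 for adipocyte, -6.43 to 0.66 for neighbouring organs, -0.46 to 0.29 for skeletal muscle, -0.82 to -0.20 for Schwann and neuron, -0.57 to 0.35 for immediate early and -0.25 to 0.0066 for hypoxia. Others ranged from 0.017 to 0.14 for clock, -0.88 to 0.25 for glucocorticoid, 0.034 to 0.28 for mitochondrial, -0.31 to 0.016 for respiratory chain and -0.13 to 0.026 for ribosomal. Called in a turned direction were glucocorticoid without WT replicate 3 (up, adjusted p = 0.0109), immediate early without VEGF/LysM replicate 1 (up, adjusted p = 0.038) and capsule without VEGF/LysM replicate 3 (up, adjusted p = 0.0202).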

Other observations

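All tests of explanations below except the counts over other splits of the samples were chosen after the result was seen.

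The real split gave 0 genes past the threshold in edgeR's test (459 at an unadjusted p under 0.05), and the highest of the other splits of the 6 libraries into 3 and 3 gave 1. For lists called by camera with the preset correlation, the real split gave 17 and the highest other split 18, and 3 of the 10 splits gave 17 or more. With 10 splits the share cannot fall under 0.05. The lowest split called 8 lists, so every split of these libraries called lists at this setting.

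Liver transcripts in WT replicate 3 were weighed first. Of 28 hepatocyte-list genes (Alb and Apoa2, seen first, left out), 27 were at least 100 times their level in WT replicates 1 and 2, which is what hepatocyte RNA in that library would bring and makes it a candidate source; the labels name no other tissue. Of 15 B cell genes, 12 were at least 3 times the highest other library, and their source was not tested. In VEGF/LysM replicate 3 the 16 liver genes at most 0.5 CPM elsewhere stood at 0.152% to 0.536% of their counts in WT replicate 3. Reads of WT replicate 3 assigned to that library in sequencing would keep 1 ratio, and chi-square per degree of freedom was 5.51 (4.71 over 13 without the near-identical Serpina1 genes). This argues against such reads as the whole source as far as counting error goes, the only error the chi-square covers. The 6 kidney markers under the same limit summed in VEGF/LysM replicate 3 to 9.90% of their counts in WT replicate 3 (95% counting interval 6.97% to 13.7%; single genes 7.77% to 19.0%). RNA or reads carried over from WT replicate 3 would have kept the ratio of the liver genes, so this argues against carry-over as the source of the kidney transcripts. For the liver transcripts, carry-over before amplification stays open. No biological explanation was tested.

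Lower Lyz2 in VEGF/LysM did not pass the test over all genes and is given as a hypothesis. Fewer macrophages as the whole cause would lower the other markers by about as much. Yet the median log2 fold change of the other 24 macrophage genes was 0.00031 (quartiles -0.11 and 0.15) against -0.94 for Lyz2. Over the fits that left out 1 library, the median of the macrophage list, Lyz2 included, ran from -0.18 to 0.046. In these fits it was called only without VEGF/LysM replicate 3 (lower, camera, adjusted p = 0.0384). Without both libraries with liver transcripts the macrophage list was also called lower (median -0.19, camera, adjusted p = 0.00936). A smaller loss of macrophages as part of the cause thus stays open. Reads moved to Lyz1 are argued against as the whole cause, since the rise of Lyz1 (10.2 CPM) was 8.79% of the fall of Lyz2 (116 CPM), and the unusual content of WT replicate 3 likewise, since Lyz2 stood at -0.88 without that library. Chance stays open too, as Lyz2 did not pass over all genes. Also open and untested is a difference at the Lyz2 locus itself between the groups, as LysM is another name of this gene. So is a lower level of Lyz2 per cell. The labels do not describe the allele, so these cannot be told apart.

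The lower erythrocyte list did not come from WT replicate 3 alone, since the list's median without it was -1.55. Without WT replicate 1 it was -0.93. The SD over the 6 libraries of log2 Hbb-bs over Hba-a1 was 0.304, against 1.09 for log2 Hba-a1 alone. Both globins would move together with red cell content of any origin, so this does not show where it came from. Blood left in the gland in different amounts and a blood content changed by the genotype cannot be told apart, since either could bring these values. Hba-a1 did not overlap between the groups, although WT replicate 2 (75.9 CPM) lay near VEGF/LysM (at most 63.4 CPM). Both explanations stay open, and the effect of the genotype was not tested.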
